A study of Mus musculus with 16 samples.

How the data were processed

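The series measured RNA from somatic cells of fetal mouse testes, wild type (WT) or knockout (KO) for Inhba, the gene of the beta A subunit of activin A, at embryonic days 13.5 and 15.5. Each of the 4 groups had 4 libraries, 16 in all. Per the labels, paired gonads were freed of mesonephros and made into single-cell suspensions, and viable GFP-negative cells were sorted away from germ cells marked by an Oct4-GFP reporter. Libraries were made with the Nugen Trio kit and sequenced on an Illumina HiSeq3000. Per the series design, cells came from 3 to 4 individual animals per age and genotype, and replicates are taken here as separate animals. With 4 libraries in each group, that count leaves open that some libraries share an animal, and p-values would then be too small. Replicate numbers were given in accession order and pair nothing between groups. The titles also carry a leading number, called the title number here, and a suffix, neither of which the labels explain. 855 stands on WT E15.5 replicate 2 and KO E15.5 replicate 3, so the number does not name 1 animal, and 1052 stands on KO E15.5 replicates 1 and 2, with different suffixes.

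The deposited table holds raw read counts per gene, whole numbers for 47729 mouse genes and 16 libraries, with no row that names no gene and no column of another series. Per the submitters' processing notes, the tools were FastQC 0.11.5, Picard 2.9.0, MultiQC 1.0, STAR 2.5.2b, Subread 1.5.2 and featureCounts (version not given in the sources used here) on the genome build GRCm38. The deposited counts are named as non-stranded, so reads from overlapping or antisense genes cannot be told apart, and near-identical copies such as Hspa1a and Hspa1b or the Stfa genes can share reads. Gene symbols and positions came from the GRCm38 annotation given with the data, which matched 47310 identifiers (99.1%). Total counts ran from 6131592 in KO E13.5 replicate 3 to 23324810 in WT E15.5 replicate 2, so low transcripts are least precise in the former. Within groups, chi-square per degree of freedom of the 24 pairs of libraries ran from 8.79 to 249 over genes with a summed count of at least 20, so every pair differed by more than sampling noise and each library was counted once.

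Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, on all 16 libraries in a design of 4 groups, after filterByExpr and TMM normalization, with Benjamini-Hochberg adjustment at 0.05. There were 5 contrasts: KO against WT at each age, the difference between those effects, and E15.5 against E13.5 in each genotype. The filter left 20076 genes. Called means an adjusted p under 0.05 in this test unless another tool is named. SE is the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, with SD over the 4 libraries of a group. Calls within 10 Mb of Inhba (5 Mb and 20 Mb as alternatives) used a two-sided Fisher's exact test, and the Inhba level also a two-sided exact permutation test.

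The 25 gene lists, the rule for the genes named and most of the other settings tried were fixed before the data were examined. The lists were TGF-beta superfamily members, activin and TGF-beta responsive genes, Sertoli cells, fetal Leydig cells, androgen and estrogen synthesis, cholesterol synthesis, fatty acid metabolism, DNA replication and mitosis, cyclins D and cell cycle inhibitors, granulosa genes, interstitial progenitor and stromal cells, peritubular myoid cells, endothelium, pericytes, macrophages, erythroid cells, germ cells, mesonephros and surface epithelium, neural crest and glia, hedgehog pathway, basement membrane and matrix, immediate early and dissociation stress genes, apoptosis and p53 targets, hypoxia and glycolysis, and Notch and Wnt ligands and receptors. Each list was tested with camera (limma 3.58.1) on log2 CPM with the preset correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation. No list kept its call with an estimated correlation in any contrast. That held also for age with 15 libraries, where 4655 genes in WT and 4350 in KO were called. The correlation is estimated from deviations within the groups of all libraries in a fit, which in the 16-library fit include KO E13.5 replicate 1. A list not called in this setting was therefore not shown to be unchanged.

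The genes named in the text were chosen by rule. In each KO against WT comparison these were Inhba, then the called genes with mean CPM of at least 2 at that age and no overlap between genotypes, at most 10 per direction by log2 fold change. Symbols of the Gm-number, Rik and -ps kinds were left out. From each list came up to 4 called members with the smallest p, or the 1 member with the smallest p where none was called. In age comparisons and the interaction the rule took 5 per direction and up to 4 called members per list.

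The other settings fixed at that point were RLE and upper quartile normalization, other filters on low counts, DESeq2 1.42.0, limma-voom without and with sample quality weights, only the groups compared, a fold-change minimum, the title number as a random block or summed, erythroid genes left out, camera with an estimated correlation, and each library left out. After seeing the data, KO E13.5 replicate 1 stood apart in germ cell transcripts. The fit of the other 15 libraries was planned as 1 of the left-out libraries, but it was set beside the 16-library fit, and combined with DESeq2, limma-voom, RLE, fewer groups, list genes left out or a further library left out, after seeing the data. That fit tested 20406 genes.

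The fits were tested on simulated counts with the real means, dispersions and library sizes and 200 changed genes per contrast, 100 by 2-fold and 100 by 4-fold. The changed genes were drawn from those with a mean of at least 2 CPM, so the recovery does not hold for lower genes. Each gene had the same dispersion in all libraries, so a single library that stands apart was not simulated. Of 20076 genes with 16 libraries, the test recovered 48 and 94 for KO against WT at E13.5, 55 and 93 at E15.5, and 13 and 76 for the difference of effects. Age in WT gave 62 and 95, and age in KO gave 50 and 93. Of 20406 genes with 15 libraries, it recovered 77 and 97 at E13.5, 74 and 100 at E15.5, 53 and 94 for the difference, 83 and 98 for age in WT and 82 and 99 for age in KO. Between 2 and 20 unchanged genes were called. The 40 or 41 other mitosis list genes, raised 2-fold in the same simulations, were called as a list by camera in each contrast, and at most 1 other list was called. Simulated genes were drawn independently, while the mitosis list had an estimated correlation of 0.49 in the real data. These list calls therefore do not show how camera with the preset correlation performs on lists whose members vary together. The submitters' reads and any results of their own were not used here.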

Results

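The data are read counts per gene from somatic cells of fetal mouse testes with (WT) or without (KO) the gene Inhba, which encodes the subunit that pairs with itself to form activin A, a signalling protein of the TGF-beta superfamily. There were 4 libraries each for WT and KO at embryonic days E13.5 and E15.5, ages at which testis cords grow and fetal Leydig cells make androgens. The design asks what the loss of activin A changes in gonadal somatic cells at each age. Total counts per library were 17919182 to 22090708 in WT E13.5, 17118853 to 23324810 in WT E15.5 and 13810303 to 22274787 in KO E15.5. In KO E13.5 they were 23215119, 16358894, 6131592 and 17857673 in replicates 1 to 4. Between 23182 and 28411 genes had a count in a library, and protein-coding genes took 87.7% to 90.8% of counts. The gene with the most counts was mt-Rnr2, a mitochondrial ribosomal RNA, at 3.75% to 6.71%.

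Markers of Sertoli cells, stromal cells, endothelium and other somatic types were detected in every library, while germ cell transcripts were scarce in 15 of the 16. In those 15, the 20 measured germ cell genes summed to between 25.7 and 76.4 CPM. KO E13.5 replicate 1 held 5349 CPM of the same genes, and each of the 20 was highest there. Its CPM was 1599 for Dazl and 398 for Ddx4, RNA-binding proteins of germ cells, 1089 for Dppa3 and 119 for Pou5f1, the gene whose reporter was used to sort germ cells away. Somatic lists were lower in this library than in the mean of the other 3 KO E13.5 libraries, by a log2 difference of -2.26 for Sertoli, -1.68 for stromal, -1.90 for endothelial, -1.87 for Leydig, -2.87 for macrophage and -1.60 for myoid markers. Its correlation with the rest of its group was 0.901, against 0.969 to 0.990 in the other libraries. Results are given for all 16 libraries, as the design was fixed, and beside them for the 15 without this library, a choice made after seeing the data.

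**Figure D1:**
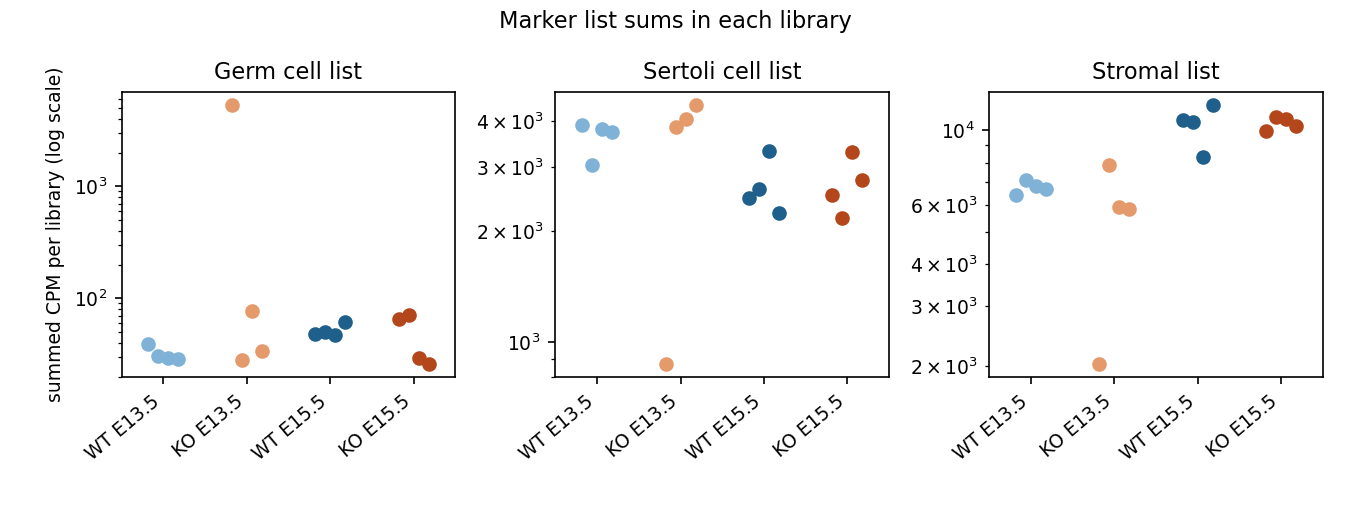
Summed CPM of the germ cell, Sertoli and stromal marker lists in each of the 16 libraries, on a log axis, 1 point per library. KO E13.5 replicate 1 stands at 5349 CPM for germ cell genes, and the other 15 libraries lie between 25.7 and 76.4.

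Inhba transcripts fell in KO at both ages. Inhba (GRCm38 chromosome 13, 16011851 to 16031621) stood at 73.3 ± 24.5 CPM (SD, n = 4) in WT E13.5 and 6.38 ± 1.83 (n = 4) in KO E13.5, and at 291 ± 68.0 (n = 4) in WT E15.5 and 42.5 ± 6.13 (n = 4) in KO E15.5. Every KO library lay below every WT library of its age, with 44 to 130 counts against 804 to 2413 at E13.5 and 638 to 992 against 3370 to 7001 at E15.5. The log2 fold change was -3.54 ± 0.28 (SE) at E13.5 (edgeR adjusted p = 1.6e-05) and -2.78 ± 0.26 at E15.5 (adjusted p = 5.1e-05). Without KO E13.5 replicate 1 the E13.5 value was -3.37 ± 0.28 (adjusted p = 2e-05). A two-sided exact permutation test gave p = 0.0286 at each age, the smallest that 4 against 4 allows. Which part of the gene was deleted is not stated in the sources used here, and counts were summed over the whole gene, so the values do not show which exons the KO reads cover.

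**Figure D2:**
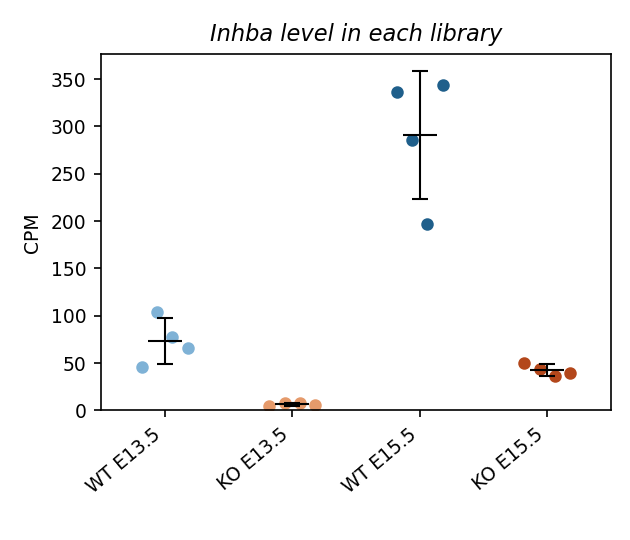
Inhba CPM in each library by group, with the mean and SD over 4 libraries. Every KO library lies below every WT library of the same age.

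At E15.5, loss of Inhba went with lower transcripts of a chemokine, a protease inhibitor and a steroid enzyme. Ccl17, a chemokine, fell 37.1-fold (log2 fold change -5.21 ± 0.43, adjusted p = 3.2e-05), from 76.0 ± 14.2 CPM in WT to 2.02 ± 0.64 in KO (SD, n = 4 each). Serpina5, a serine protease inhibitor, fell 7.32-fold (-2.87 ± 0.41, adjusted p = 0.0065), from 42.5 to 75.9 CPM in the WT libraries to 6.46 to 9.94 in KO. Hsd17b1, a hydroxysteroid dehydrogenase of sex steroid synthesis, fell 5.95-fold (-2.57 ± 0.44, adjusted p = 0.024), from 26.8 ± 5.89 to 4.49 ± 2.47 CPM. AF529169 fell 8.30-fold (-3.05 ± 0.28, adjusted p = 4.8e-05), to 1.85 CPM in KO. Smaller decreases were called for Pex5l (log2 fold change -2.29 ± 0.34), Il22ra1, an interleukin receptor subunit (-1.94 ± 0.31), Kcne1, a potassium channel subunit (-1.79 ± 0.30), Shank2, a synaptic scaffold protein (-1.40 ± 0.26), and Zfhx2, a zinc finger homeobox factor (-1.28 ± 0.16), with adjusted p between 0.0016 and 0.042. These genes lie on several chromosomes, with Ccl17 on chromosome 8 (94810453 to 94812036), AF529169 on 9 (89587216 to 89623125), Serpina5 on 12 (104101113 to 104106137) and Hsd17b1 on 11 (101078411 to 101080527).

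Genes higher in KO at E15.5 included a neuregulin receptor and developmental regulators. Erbb3, a receptor tyrosine kinase for neuregulins (chromosome 10, 128567523 to 128589652), rose 3.77-fold (log2 fold change 1.91 ± 0.17, adjusted p = 4.5e-05), from 12.5 ± 1.69 to 46.9 ± 10.8 CPM (SD, n = 4 each). Tbx22, a T-box transcription factor, rose 12.6-fold from a low level (3.65 ± 0.45, adjusted p = 0.0016). Hprt, the purine salvage enzyme encoded on chromosome X (52988137 to 53021659), rose 2.26-fold (1.18 ± 0.17, adjusted p = 0.0075), from 41.3 ± 2.59 to 93.4 ± 20.0 CPM. Wif1, a secreted inhibitor of Wnt proteins, rose to 4.43 CPM in KO (1.56 ± 0.24, adjusted p = 0.013), and Slc9a2, a sodium and proton exchanger, rose from 0.604 to 4.88 CPM (3.01 ± 0.45, adjusted p = 0.0095). The other named increases were Npbwr1, a neuropeptide receptor (3.07 ± 0.57), Trpm3, a cation channel (2.20 ± 0.37), and BC006965 (2.15 ± 0.40), with adjusted p between 0.021 and 0.046. Across 28 settings, AF529169, Ccl17, Erbb3, Hprt, Pex5l, Serpina5, Tbx22 and Zfhx2 passed the threshold in all 28, Slc9a2 and Wif1 in 25, Il22ra1 in 22, Trpm3 in 21, Hsd17b1 in 20, Kcne1 in 19, Shank2 in 15, Npbwr1 in 12 and BC006965 in 11.

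**Figure D3:**
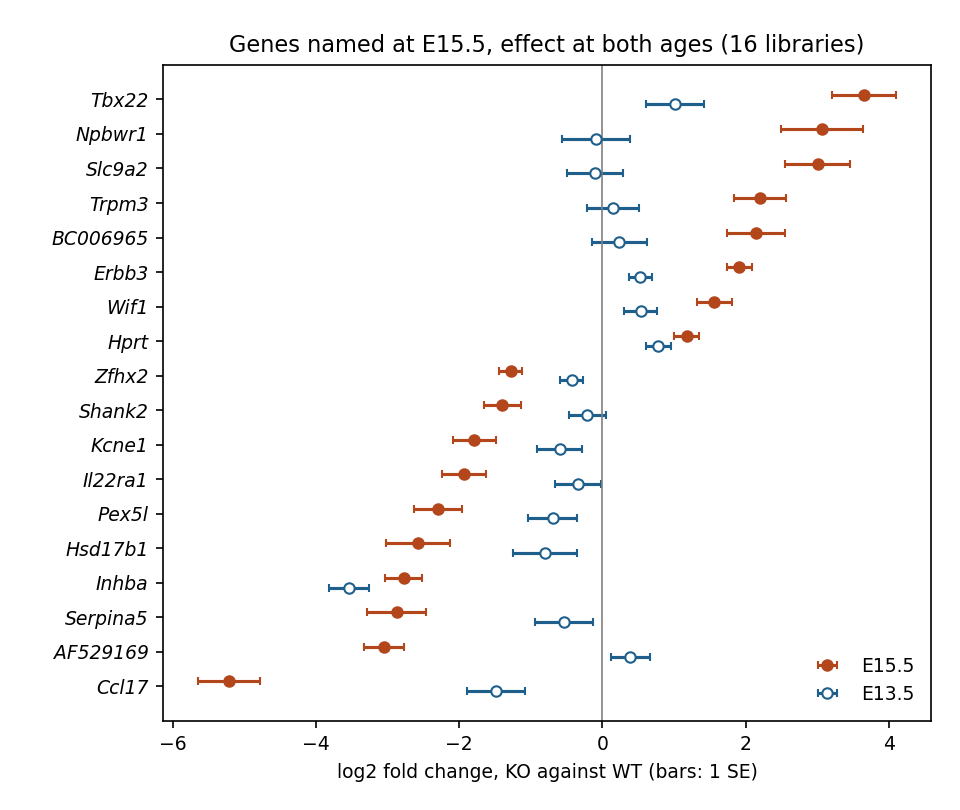
Log2 fold change (KO against WT) with 1 SE at E15.5 (filled points) and E13.5 (open points) for the 18 genes named at E15.5, fitted on 16 libraries. Ccl17 lies at -5.21 at E15.5 and -1.48 at E13.5, and Erbb3 at 1.91 and 0.53.

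In all, 30 of 20076 genes were called at E15.5 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11 higher and 19 lower, and 1002 had an unadjusted p under 0.05. DESeq2 called 106, limma-voom with sample quality weights 546 and edgeR on the 8 E15.5 libraries alone 171, and summing the 2 KO E15.5 libraries that share a title number left 13. Without KO E13.5 replicate 1, which enters this comparison through the shared estimate of the spread, the filter and the normalization, 306 genes were called, 130 higher and 176 lower, and these included all 30. The median SE over genes was 0.271 with 16 libraries and 0.183 with 15. Leaving out 1 other library from the 16 gave 12 genes without WT E15.5 replicate 1, 14 without replicate 2 and 19 without replicate 4, and 12, 14, 19 and 15 without KO E15.5 replicates 1 to 4. From the 15 libraries it gave 173 without WT E15.5 replicate 1 and 162 without KO E15.5 replicate 4.

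The 15-library fit added members of several cell type lists at E15.5. Among Sertoli genes, Cldn11, a tight junction protein (log2 fold change 1.99 ± 0.25, adjusted p = 0.00041), Aard (1.15 ± 0.22, adjusted p = 0.012) and Wt1, a transcription factor (0.38 ± 0.08, adjusted p = 0.029), rose. Sox10, a neural crest factor (0.83 ± 0.15), Tgfbi, a matrix protein induced by TGF-beta (0.78 ± 0.13), and Upk3b, a surface epithelium marker (0.84 ± 0.20), were also called higher, with adjusted p between 0.0032 and 0.048. Inha, the inhibin alpha subunit, fell from 84.7 to 27.3 CPM (-1.63 ± 0.22, adjusted p = 0.00055), and Hsd17b3, which makes testosterone, from 225 to 126 CPM (-0.84 ± 0.20, adjusted p = 0.044). Ccnd2, cyclin D2, fell from 459 to 236 CPM (-0.96 ± 0.11, adjusted p = 0.00012), as did the mitotic genes Ccnb1 (-0.42 ± 0.09, adjusted p = 0.022) and Cdk1 (-0.40 ± 0.09, adjusted p = 0.037). None of these was called with 16 libraries.

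As groups, 2 of the 25 gene lists were called at E15.5 by camera on 16 libraries. DNA replication and mitosis genes were lower as a list, with 6 of 41 members positive and a median log2 fold change of -0.12 (adjusted p = 0.000533), although none was called singly by edgeR and 5 had an unadjusted p under 0.05. Notch and Wnt ligands and receptors were higher, with 24 of 30 positive and a median of 0.10 (adjusted p = 0.0426), and Wif1 was the 1 member called. That list was not called without WT E15.5 replicate 1 (adjusted p = 0.124) or KO E15.5 replicate 2 or 3 (0.0801 each). With all 16 libraries and an estimated correlation the adjusted p was 0.992 for both lists and for each of the 25. With 15 libraries the mitosis list gave adjusted p = 8.86e-07 (2 members called lower, 13 lower adjusted over the list alone), the Notch and Wnt list 0.0163 (1 higher; 4 higher and 1 lower adjusted over the list alone) and the myoid list, called higher there, 0.0104 (0 members called, 2 at an unadjusted p under 0.05 and 1 higher adjusted over the list alone). For those lists the adjusted p was 0.945 with an estimated correlation.

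The other 23 lists did not pass at E15.5 with 16 libraries. Among the main cell types, Sertoli markers had 13 of 29 members positive (median -0.10, mean 0.02, camera direction down, adjusted p = 0.951), fetal Leydig markers 4 of 23 (median -0.26, adjusted p = 0.135), stromal markers 15 of 25 (median 0.11, adjusted p = 0.23), myoid markers 12 of 14 (median 0.21, adjusted p = 0.0575), endothelial markers 16 of 18 (median 0.20, adjusted p = 0.0769) and pericyte markers 5 of 9 (median 0.06, adjusted p = 0.883). Lists of other cell types gave 14 of 18 for macrophages (median 0.07, adjusted p = 0.532), 4 of 13 for erythroid cells (median -0.43, adjusted p = 0.954), 6 of 20 for germ cells (median -0.14, adjusted p = 0.7), 9 of 16 for mesonephros and surface epithelium (median 0.09, adjusted p = 0.232) and 12 of 15 for granulosa genes (median 0.23, adjusted p = 0.0769). Neural crest and glial markers had 4 of 8 positive (median -0.02, mean 0.33, direction up, adjusted p = 0.486), with Erbb3 the 1 member called. For steroids and lipids the values were 12 of 26 for androgen and estrogen enzymes (median -0.03, adjusted p = 0.532, with Hsd17b1 called lower), 9 of 31 for cholesterol synthesis (median -0.13, adjusted p = 0.365) and 24 of 39 for fatty acid metabolism (median 0.05, adjusted p = 0.532).

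Signalling lists at E15.5 gave 19 of 31 positive for TGF-beta superfamily members (median 0.04, mean -0.09, direction down, adjusted p = 0.982, with Inhba called lower), 8 of 19 for activin and TGF-beta responsive genes (median -0.16, adjusted p = 0.486) and 11 of 14 for the hedgehog pathway (median 0.07, adjusted p = 0.532). Matrix genes had 19 of 31 positive (median 0.03, adjusted p = 0.23), cyclins D and inhibitors 9 of 15 (median 0.07, adjusted p = 0.632), apoptosis genes 13 of 24 (median 0.02, mean -0.01, direction up, adjusted p = 0.896) and hypoxia genes 5 of 22 (median -0.15, adjusted p = 0.0769). Immediate early and dissociation stress genes had 1 of 22 positive (median -0.56, adjusted p = 0.0575), and their mean log2 CPM was 7.04 in WT E15.5 replicate 3 against 5.27 to 5.84 in the other WT and 5.09 to 5.66 in the KO libraries of that age. Adjusted over the list alone, members passed in 5 of the 25 lists with 16 libraries: 2 lower TGF-beta superfamily genes (Inhba and Inha), 1 higher Sertoli gene (Cldn11), 1 lower androgen and estrogen enzyme, 1 higher and 1 lower neural crest gene and 1 higher Notch and Wnt gene. With 15 libraries, adjusted over the list alone, 6 Sertoli members were higher and 8 lower, 1 Leydig member was higher and 4 lower, and 5 stromal members were higher.

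At E13.5, Inhba was the only gene called in KO against WT, with 16 or with 15 libraries. Genes called at E15.5 had smaller values here that did not pass: Ccl17 -1.48 ± 0.40 (log2, SE; adjusted p = 0.23), Erbb3 0.53 ± 0.16 (0.236), Hprt 0.78 ± 0.17 (0.23), Tbx22 1.02 ± 0.40 (0.278), Hsd17b1 -0.80 ± 0.45 (0.41) and Serpina5 -0.54 ± 0.41 (0.543). Without KO E13.5 replicate 1 these were -1.19 (adjusted p = 0.225) for Ccl17, 0.56 (0.218) for Erbb3, 0.62 (0.198) for Hprt, 1.35 (0.179) for Tbx22, -0.42 (0.637) for Hsd17b1 and -0.17 (0.869) for Serpina5. Macrophage markers had log2 fold changes above 0 for 18 of 18 members in the 15-library fit (median 0.72), led by Laptm5, a lysosomal membrane protein of blood cells, at 1.28 ± 0.27 (adjusted p = 0.17). Their mean log2 CPM was 1.54 to 1.98 in WT E13.5 and 2.27 to 2.69 in KO E13.5 replicates 2 to 4, and -0.13 in replicate 1. The edgeR test gave 2978 genes with an unadjusted p under 0.05 with 16 libraries and 2462 with 15. DESeq2 called 53 genes with 16 libraries and 168 with 15, and limma-voom 1 with either. Without KO E15.5 replicate 1 the 16-library count was 2, and from the 15 libraries it was 2 without WT E13.5 replicate 4 or KO E13.5 replicate 3.

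Of the 7 lists called at E13.5 with 16 libraries, 6 lost the call or turned direction without KO E13.5 replicate 1, and the cholesterol list was called in the same direction in both fits. With 16 libraries, germ cell genes were higher (20 of 20 positive, median 4.39, adjusted p = 1.03e-06), as were mitosis genes (34 of 41, median 0.16, adjusted p = 0.0136) and cholesterol genes (20 of 31, adjusted p = 0.0299). Stromal (4 of 25 positive, median -0.27, adjusted p = 0.00301), hedgehog (0 of 14, median -0.31, adjusted p = 0.00301), matrix (6 of 31, median -0.19, adjusted p = 0.00815) and Sertoli genes (6 of 29, median -0.10, adjusted p = 0.0297) were lower. With an estimated correlation each of these had adjusted p = 0.966. Leaving out another library from the 16, cholesterol genes were not called without WT E13.5 replicate 1 (adjusted p = 0.156) or 3 (0.0587) or KO E13.5 replicate 2 (0.182) or 4 (0.298), nor Sertoli genes without WT E13.5 replicate 1 (0.072), 3 (0.0804) or 4 (0.0506), mitosis genes without WT E13.5 replicate 3 (0.052) or KO E13.5 replicate 3 (0.0593) and matrix genes without WT E13.5 replicate 3 (0.0519). No member of these lists was called by edgeR over all genes. An unadjusted p under 0.05 was found for 19 germ cell, 7 mitosis and 5 cholesterol genes and for 1 gene each of the stromal, hedgehog, matrix and Sertoli lists, and 19 germ cell genes were higher adjusted over the list alone. Mael and Cdh1, which germ cells express, stood at 8.68 ± 1.99 and 6.45 ± 1.53, both with adjusted p = 0.23.

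Without that replicate, 6 lists were called at E13.5, each higher in KO: macrophage genes (adjusted p = 4.2e-08), immediate early genes (21 of 22 positive, median 0.38, adjusted p = 0.00426), Sertoli genes (24 of 29, median 0.20, adjusted p = 0.00785), fatty acid genes (31 of 39, median 0.13, adjusted p = 0.0268), cholesterol genes (24 of 31, median 0.17, adjusted p = 0.0344) and neural crest genes (5 of 8, median 0.47, adjusted p = 0.0458). With an estimated correlation the adjusted p was 0.844 for each. The Sertoli list had the opposite direction in the 2 fits. Adjusted over the list alone, 9 macrophage, 3 neural crest and 1 immediate early gene were higher, and none over all genes by edgeR. At an unadjusted p under 0.05 there were 9 macrophage, 3 immediate early, 3 Sertoli, 5 fatty acid, 2 cholesterol and 3 neural crest genes. The immediate early gene was Hspa1b, a heat shock protein (2.86 ± 0.79, adjusted p = 0.21 over all genes), which can share reads with its near-identical copy Hspa1a. Immediate early genes had a mean log2 CPM of 7.17 in WT E13.5 replicate 4, above the 5.77 to 6.94 of KO E13.5 replicates 2 to 4, and 5.18 to 5.70 in the other WT libraries of that age. Germ cell genes gave adjusted p = 0.067 in this fit. Their mean log2 CPM was 1.17 in KO E13.5 replicate 3, but -0.39 and -0.24 in replicates 2 and 4, against -0.48 to -0.33 in WT E13.5.

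Inhba, the gene knocked out in both comparisons, was the 1 gene called by edgeR at both ages, with 16 or with 15 libraries. Of the other 29 genes called at E15.5, 23 (79.3%) had the same sign at E13.5, against 52.3% of all genes, and the comparisons share no libraries. Their median absolute log2 fold change was 2.20 at E15.5 and 0.43 at E13.5. With 15 libraries the share was 249 of 305 (81.6%), against 60.8% of all genes. Within 10 Mb of Inhba, 0 of 132 genes other than Inhba were called at E15.5 and 29 elsewhere (0.146%, two-sided Fisher's exact p = 1). The window was set because the allele may carry flanking sequence of another strain. With so low a share elsewhere, 0 among 132 genes would be common by chance, so the test excludes no moderate excess. In that window 4 genes had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The 15-library fit called 1 there (0.758% against 1.49% elsewhere, Fisher's exact p = 1). That gene, Hist1h2bp, was named after its values were seen, and in the 15 libraries DESeq2 called 3 genes in the window and limma-voom 2.

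The effect of genotype differed between the ages for 4 genes. Ccl17 had a more negative effect at E15.5 than at E13.5, with a log2 difference of -3.73 ± 0.56 (adjusted p = 0.035), and so did AF529169 (-3.45 ± 0.38, adjusted p = 0.0023). Cttnbp2, a cortactin-binding protein, had a difference of 2.20 ± 0.30 (adjusted p = 0.019), from -1.24 ± 0.22 at E13.5 and 0.96 ± 0.21 at E15.5, neither of which passed alone. Gm43843, named after its values were seen, had 2.37 ± 0.37 (adjusted p = 0.0455). With 15 libraries 18 genes were called, 6 higher and 12 lower, which included the 4, and among them were Erbb3 (1.36 ± 0.22, adjusted p = 0.028), Slc9a2 (2.78 ± 0.42), Npbwr1 (2.82 ± 0.52), Serpina5 (-2.70 ± 0.39, adjusted p = 0.013), Pdgfa, a growth factor (-1.40 ± 0.24), and Ccnd2 (-0.93 ± 0.16, adjusted p = 0.028). An unadjusted p under 0.05 was reached by 1273 genes with 16 libraries and 1429 with 15, and DESeq2 called 17 and 79. From the 16 libraries the count was 1 without KO E13.5 replicate 4, WT E15.5 replicate 1 or 4, or KO E15.5 replicate 1 or 2, and 2 without WT E13.5 replicate 1 or 4, KO E13.5 replicate 3, WT E15.5 replicate 2 or 3, or KO E15.5 replicate 3 or 4. From the 15 it was 11, 9 and 6 without WT E13.5 replicates 2, 3 and 4, then 4, 6 and 6 without KO E13.5 replicates 2, 3 and 4. It was 11 and 9 without WT E15.5 replicates 1 and 2, and 6, 11 and 6 without KO E15.5 replicates 1, 2 and 4.

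As lists, mitosis (adjusted p = 2.95e-06), germ cell (5.59e-06) and cholesterol genes (0.00563) had a lower effect at E15.5 than at E13.5 by camera on 16 libraries, and stromal (0.000339), Notch and Wnt (0.000529), matrix (0.000631), hedgehog (0.00112) and myoid genes (0.00223) a higher one. The lowest adjusted p with an estimated correlation was 0.786. The germ cell and stromal differences draw on KO E13.5 replicate 1, without which neither list was called at E13.5 (adjusted p = 0.067 and 0.564). Mitosis (0.477), hedgehog (0.304) and matrix genes (0.2) also lost their E13.5 call without it, with the mitosis and matrix directions turned. Myoid and Notch and Wnt levels were lowest of the group in that library too, at a mean log2 CPM of 3.15 and 3.54. With 15 libraries 12 lists were called, among them immediate early (adjusted p = 1.53e-05), macrophage (5.43e-05), mitosis (0.000684) and Leydig genes (0.00869), each with a lower effect at E15.5, while matrix (0.843) and myoid genes (0.115) were not called and hedgehog and Notch and Wnt genes were at 0.0476 each. The lowest adjusted p with an estimated correlation was then 0.689. For 2 of these lists WT E15.5 replicate 3 lay above the other E15.5 libraries. Its mean log2 CPM was 6.42 for Leydig genes (5.27 to 5.56 in the other WT, 5.29 to 5.63 in KO). For immediate early genes it was 7.04 (5.27 to 5.84 and 5.09 to 5.66). Left out of the 16 libraries, it gave camera adjusted p = 0.841 and 0.94 for these lists at E15.5. At E13.5, WT replicate 4 had the highest immediate early level (7.17).

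**Figure D4:**
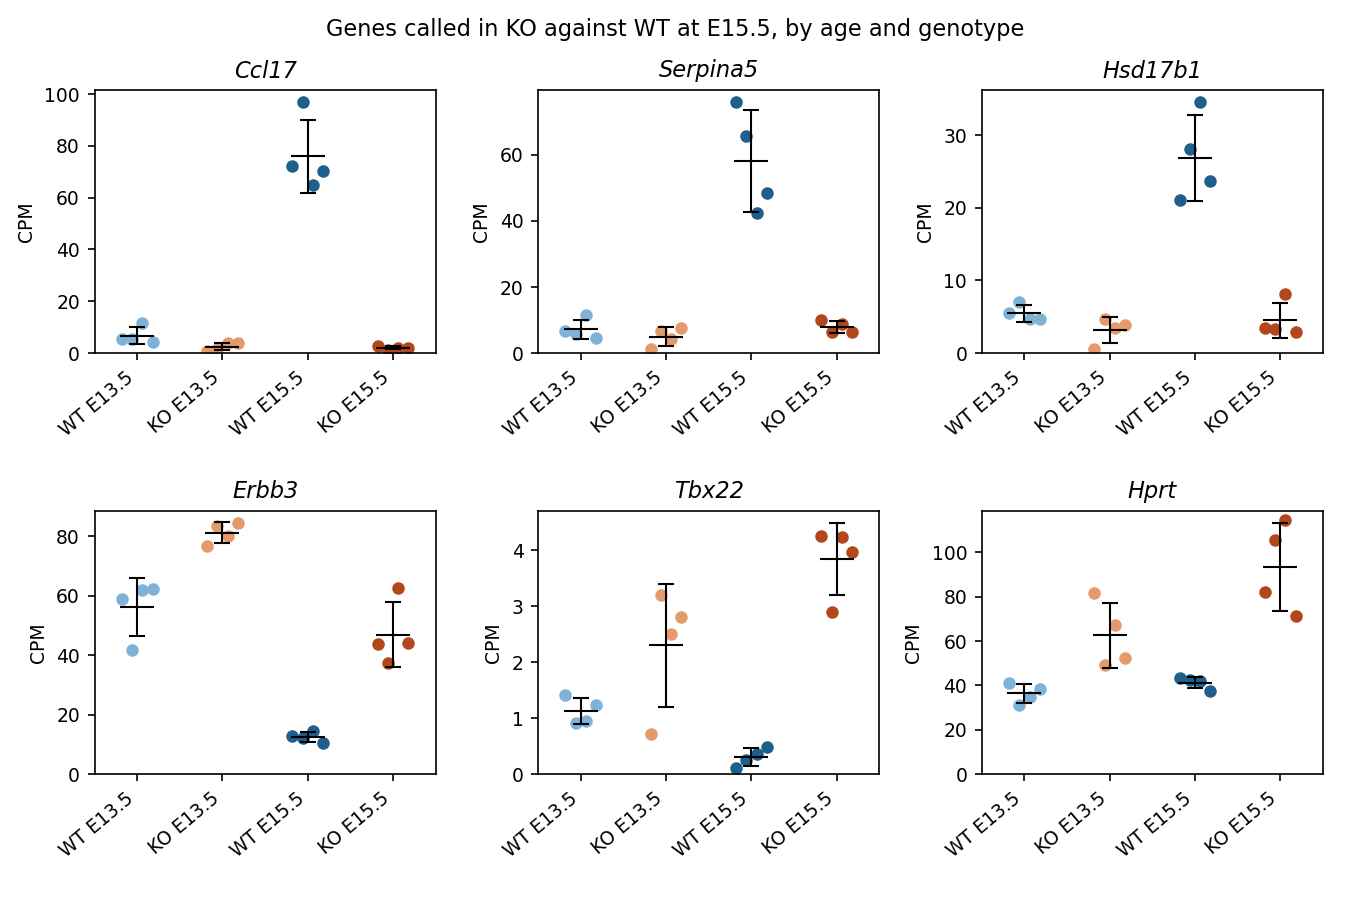
CPM of Ccl17, Serpina5, Hsd17b1, Erbb3, Tbx22 and Hprt in each library by age and genotype, with the mean and SD over 4 libraries. At E15.5 Ccl17 was 76.0 CPM in WT and 2.02 in KO, and Erbb3 was 12.5 and 46.9.

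From E13.5 to E15.5 in WT, Myh11, smooth muscle myosin (log2 fold change 1.84 ± 0.32, adjusted p = 0.0028), Dcn, decorin (1.84 ± 0.32, adjusted p = 0.003), Ebf1, a pericyte marker (2.08 ± 0.28, adjusted p = 0.00052), Lama2, a laminin chain (2.19 ± 0.31, adjusted p = 0.00072), and Lyz2, a lysozyme of myeloid cells (3.27 ± 0.67, adjusted p = 0.0086), were higher at E15.5. Inhba itself rose (1.99 ± 0.25, adjusted p = 0.00033), as did Hsd17b1 (2.30 ± 0.44, adjusted p = 0.0055). Col2a1 and Col9a1, cartilage collagens, fell by 5.12 and 5.18 on the log2 scale, and the embryonic globin Hbb-y went from 4557 to 152 CPM (-4.91 ± 1.33, adjusted p = 0.036). Hsd3b6, a steroid dehydrogenase of Leydig cells, went from 74.9 to 3.22 CPM (-4.55 ± 1.06, adjusted p = 0.018), and Erbb3 (-2.17 ± 0.17, adjusted p = 1.6e-05) and the Wnt inhibitors Dkk1 (-3.22 ± 0.38) and Wif1 (-1.49 ± 0.24) fell. Among named genes the largest increases were in neutrophil genes, Fcnb (7.73 ± 1.20), Ngp (7.14 ± 1.17) and Lcn2 (6.91 ± 1.19), and in Stfa1 and Stfa3, copies of stefin A that can share reads.

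By group, 10 lists were called for age in WT with 16 libraries. Cholesterol genes were higher (adjusted p = 4.3e-05, 5 members called and 11 adjusted over the list alone), with Lss, an enzyme of sterol synthesis, at 1.05 ± 0.19. Their mean log2 CPM was 6.08 in WT E15.5 replicate 3, 5.47 to 5.54 in the other WT E15.5 libraries and 5.08 to 5.43 in WT E13.5. Macrophage (adjusted p = 7.66e-05, 3 called and 13 adjusted over the list alone), pericyte (0.0105, 2 and 2) and myoid genes (0.0198, 3 and 5) were also higher. Endothelial (adjusted p = 0.000136, 3 members lower and 6 adjusted over the list alone), erythroid (0.00883, 3 and 3), Sertoli (0.0132, 2 and 4), Notch and Wnt (0.0452, 5 and 5) and hypoxia genes (0.0452, 0 and 0, with 5 at an unadjusted p under 0.05) were lower. Granulosa genes were lower as a list (adjusted p = 0.0132), with 1 member called higher and 2 lower over all genes and 2 higher and 6 lower adjusted over the list alone. Of these 10 lists the lowest adjusted p with an estimated correlation was 0.701. The called Sertoli members were Cldn11 (-1.58 ± 0.41, adjusted p = 0.031) and Aard (-1.46 ± 0.40, adjusted p = 0.038), both of which were higher in KO at E15.5 in the 15-library fit. Erythroid levels varied widely within groups, with a mean log2 CPM of 0.54 to 4.77 in WT E15.5 and 3.21 to 5.63 in WT E13.5.

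Age changed 1364 genes in WT with 16 libraries, 834 higher and 530 lower, and 4410 had an unadjusted p under 0.05. Fitted on the 8 WT libraries alone 4560 were called, and limma-voom with sample quality weights called 6441. Without KO E13.5 replicate 1, 4655 genes were called, 2462 higher and 2193 lower, and they included all 1364. Leaving out 1 other library from the 16 gave 597, 680 and 649 without WT E13.5 replicates 1, 3 and 4, and 568, 811 and 786 without WT E15.5 replicates 1, 2 and 4. With 15 libraries 11 lists were called, with the lowest adjusted p at 0.638 with an estimated correlation. There the Sertoli list was lower (adjusted p = 0.000294) with 1 member called higher and 12 lower, and the Notch and Wnt list was not called (adjusted p = 0.112).

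In KO over the same interval, Myh11 (log2 fold change 2.21 ± 0.32, adjusted p = 0.00085), Dcn (2.29 ± 0.33), Lama2 (2.30 ± 0.31) and Lyz2 (2.56 ± 0.65) were higher at E15.5, as was Fmo2, a monooxygenase (3.92 ± 0.58, adjusted p = 0.00085). These values include KO E13.5 replicate 1, whose myoid and stromal lists lay lower than in the rest of its group (log2 difference -1.6 and -1.68). Their sizes can therefore not be set against those in WT. The remaining Inhba reads rose too (2.75 ± 0.27, adjusted p = 8.5e-05). Erbb3 fell (-0.79 ± 0.16, adjusted p = 0.0074), as did the glycolysis genes Pkm (-1.09 ± 0.20) and Aldoa (-0.75 ± 0.12). Hbb-y (-6.40 ± 1.43) and Utf1, a germ cell gene (-6.46 ± 1.32), were among the largest decreases, and Utf1 had -2.39 (adjusted p = 0.00103) without KO E13.5 replicate 1. Without that replicate Inha (-1.07 ± 0.23, adjusted p = 0.0043) and Inhbb, the beta B subunit (-0.65 ± 0.13), were called lower, and Pdlim3, a muscle protein (3.72 ± 0.36), higher.

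The called lists for age in KO with 16 libraries were 10. Myoid (adjusted p = 7.21e-05, 9 members called higher and 10 adjusted over the list alone), stromal (0.000317, 11 higher and 2 lower; 13 and 2 adjusted over the list alone), macrophage (0.000448, 4 higher and 6 adjusted over the list alone), matrix (0.000594, 8 higher and 1 lower; 9 and 1 adjusted over the list alone), pericyte (0.00335, 2 higher and 5 adjusted over the list alone) and hedgehog genes (0.0496, 1 higher and 1 adjusted over the list alone) were higher. Hypoxia (adjusted p = 0.00335, 4 lower and 9 adjusted over the list alone), mitosis (0.00615, 3 lower and 1 adjusted over the list alone), germ cell (0.0123, 14 lower and 18 adjusted over the list alone) and erythroid genes (0.0194, 3 lower and 3 adjusted over the list alone) were lower. The lowest adjusted p with an estimated correlation was 0.87. With 15 libraries 14 lists were called (lowest adjusted p 0.452 with an estimated correlation). Sertoli genes were then lower (adjusted p = 6.92e-08, 16 members called lower and 19 adjusted over the list alone), while mitosis (adjusted p = 0.32), matrix (0.32), hedgehog (0.573) and germ cell genes (0.837) were not called.

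In KO, 3084 genes were called for age with 16 libraries, 1508 higher and 1576 lower, and 6718 had an unadjusted p under 0.05. Fitted on the 8 KO libraries alone 336 were called, and limma-voom with sample quality weights called 5184. Without KO E13.5 replicate 1 there were 4350, 2127 higher and 2223 lower, and 2516 genes were called in both fits. From the 16 libraries the count was 1285, 1325, 2015 and 1698 without KO E15.5 replicates 1 to 4, and from the 15 it was 2491 without KO E13.5 replicate 4. In WT and KO alike, 833 genes were called for age, 832 of them in the same direction. Of these 573 were higher and 259 lower, where independent lists would share 62.6 and 41.6, and the comparisons share no libraries. With 15 libraries 2634 genes were shared, 2626 in the same direction, 1317 higher and 1309 lower, against 257 and 239 for independent lists.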

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

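Chosen only after the result was seen were the tests of the germ cell transcripts in KO E13.5 replicate 1, the tests of Sertoli share and embryo stage for the age pattern, the tests of a cassette and of germ cells for Hprt, and the values from 15 libraries.

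A library was singled out where its gap to the nearest of its group as a share of the group's range exceeded Dixon's 95% critical value for 4 samples, which chance gives in about 1 of 20 groups. Of 188 groups of values, 17 met this, where 9.4 would by chance, and 7 of the 17 were KO E13.5 replicate 1. In that library the mitochondrial rRNA share was 6.33% (others 7.40% to 7.62%). Its mean log2 CPM was 4.14 for Sertoli markers (6.18 to 6.37), 4.02 for Leydig markers (5.77 to 5.94), 3.89 for androgen and estrogen enzymes (5.09 to 5.12) and -0.13 for macrophage markers (2.27 to 2.69). Its log2 CPM was -0.46 for Hsd17b1 (1.85 to 2.27) and -0.29 for Tbx22 (1.38 to 1.72).

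Other libraries stood apart in single values. WT E15.5 replicate 3 had a mean log2 CPM of 6.08 for cholesterol genes (others 5.47 to 5.54), 5.11 for fatty acid genes (4.64 to 4.69) and 4.49 for apoptosis genes (4.11 to 4.16). KO E15.5 replicate 2 had 4.74 for fatty acid genes (4.83 to 4.84) and a log2 CPM of 1.03 for Npbwr1 (2.11 to 2.27), and KO E15.5 replicate 3 had 3.05 for Hsd17b1 (1.61 to 1.83). WT E13.5 replicate 2 had -0.48 for germ cell genes (-0.34 to -0.33) and 5.39 for Erbb3 (5.88 to 5.96). WT E13.5 replicate 3 had 7.41 for matrix genes (7.27 to 7.29), and WT E13.5 replicate 4 had 4.71 for hypoxia genes (4.28 to 4.33).

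The effect of genotype differed between ages, by the interaction test, for Cttnbp2 (log2 difference 2.20), Ccl17 (-3.73), AF529169 (-3.45) and Gm43843 (2.37). By camera it differed for the lists of mitosis (adjusted p = 2.95e-06), germ cell (5.59e-06), stromal (0.000339), Notch and Wnt (0.000529), matrix (0.000631), hedgehog (0.00112), myoid (0.00223) and cholesterol genes (0.00563). With an estimated correlation the adjusted p was 0.786 or more for each. With 15 libraries the matrix (0.843) and myoid lists (0.115) were not called, and the hedgehog and Notch and Wnt lists were at 0.0476 each (0.689 with an estimated correlation). The germ cell and stromal differences draw on KO E13.5 replicate 1. Its germ cell genes summed to 5349 CPM (76.4 at most elsewhere). Its stromal mean log2 CPM was 4.96 (6.21 to 6.57 in the other KO E13.5 libraries). At E13.5 neither list was called by camera without it (adjusted p = 0.067 and 0.564). Mitosis (0.477), hedgehog (0.304) and matrix genes (0.2) lost their E13.5 call in the same way. Mean log2 CPM in that library was 6.98 for mitosis (6.1 to 6.39 in the other KO E13.5 libraries), 4.89 for hedgehog (5.91 to 6.32) and 5.9 for matrix genes (7.2 to 7.51). For myoid genes it was 3.15 (4.5 to 4.9), and for Notch and Wnt genes 3.54 (4.2 to 4.59).

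KO E13.5 replicate 1 held germ cell transcripts at 70 times the highest sum of the other 15 libraries, although per the labels germ cells were sorted away by their reporter. A pure germ cell library under a wrong label is argued against by the Sertoli genes, whose median ratio to the other 3 KO libraries was 0.202 (95% bootstrap interval over genes 0.193 to 0.242, 29 genes). That ratio bears only on a library without somatic cells, so a wrong label on a library of mixed cells stays open. An effect of the knockout at this level is argued against by the other 3 KO E13.5 libraries, at 76.4 CPM at most (5349 in replicate 1, 29.0 to 39.1 in WT). A smaller effect stays open (15 libraries, 17 of 20 genes positive, median log2 fold change 0.76, camera adjusted p = 0.067, and 0.844 with an estimated correlation). Of those KO libraries only replicate 3, the library with the fewest counts, lay above WT E13.5. Replicates 2 and 4 had 27.9 and 33.9 CPM. Germ cells beside somatic cells in KO E13.5 replicate 1 stay as a candidate explanation. Each of the 20 germ cell genes was highest there (Dazl at 1599 CPM), none of them on another list. The Sertoli, stromal, endothelial, Leydig, macrophage and myoid lists were lower. The summed CPM of mesonephros and surface epithelium markers was higher (471 against 188.5 to 244.4 in the other 3 KO E13.5 libraries). That sum rested mainly on Cdh1 (245.8), which germ cells express, and Epcam (168), while the list's mean log2 CPM was lower (2.02 against 2.18 to 2.55). How germ cells would have come to be in this library was not tested.

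At E15.5, 279 of the 306 genes called in KO with 15 libraries (91.2%, against 68.2% of all genes) had a sign opposite to the WT change with age, and both comparisons use the WT E15.5 libraries. Across 14859 genes the covariance of the changes was -0.0732 (correlation -0.456), where simulation without a genotype effect gave -0.0235 (-0.032 to -0.0172). Simulated genes varied independently, so that range leaves out shifts that many genes of a library share. With the WT libraries divided between the comparisons the covariance was -0.0478. A larger share of Sertoli cells in KO was not decided, since its markers had a median of -0.10 (95% bootstrap interval -0.38 to 0.16) but went both ways, with 6 higher and 8 lower adjusted over the list alone. Sharing of the WT libraries alone was expected to give a covariance of -0.0255, part of the full value. In the divided covariance no WT E15.5 library stands on both sides, so sharing does not produce it. Delayed maturation in KO, KO embryos collected at a younger stage and chance differences between libraries cannot be told apart. The divided covariance stayed negative, as both maturation and stage would give. However, 5 of 70 labellings of the E15.5 libraries were as low (lowest other -0.0759, median 0.00321). The bound written beforehand, that 4 or more labellings as low would speak against delayed maturation, was met. Its reading was changed after the result to undecided, because missing such a bound with 4 libraries per group excludes no effect while the divided covariance lies below 0. The same bound had been written beforehand as the prediction of the shared WT libraries. That prediction was met. The labellings measure chance between libraries and not sharing, so the bound does not show how much sharing contributes. This reading departs from what was written.

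Hprt was higher in each KO than in each WT library at both ages, with a lowest KO over highest WT ratio of 1.2 at the closer age. A change of its whole neighbourhood is argued against by the 30 tested genes within 2 Mb, with a median log2 change of -0.04 (95% bootstrap interval -0.15 to 0.01) at E15.5, and germ cells in KO libraries by sums that overlap between genotypes (highest WT over lowest KO 2.4). A candidate explanation is transcript from an Hprt selection cassette in the targeted allele, a hypothesis that the counts fit but that was not tested on reads, and the labels do not describe the allele. A response of Hprt to the loss of activin A stays open and untested.

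Other divisions of the same libraries into groups of the same sizes were tested for whether chance can be excluded as the source of each count. With 16 libraries, 1 of 35 splits (the real one) gave as many genes at E15.5 (30 genes, highest other 1), for age in WT (1364, highest other 1) and for age in KO (3084, highest other 29). That is the smallest share 35 splits can give, and it excludes chance at under 0.05 only if the libraries are separate animals. The splits treat libraries as exchangeable, which fails if some share an animal. At E13.5 the real split was also the 1 of 35 with a call (highest other 0), but its 1 gene was Inhba, the gene knocked out, so this says nothing of a further response to the knockout. For the difference of effects 4 of 100 splits gave as many (4 genes, highest other 8), and with 15 libraries 3 of 100 did (18 genes, highest other 53), shares under 0.05 as well. In the highest of each, all E15.5 genotypes were exchanged, which keeps the E15.5 effect with its sign turned. Neither is therefore a split without an effect. Genotypes at E13.5 were shuffled as well, and the E13.5 labels of those splits were not kept. Because both ages were shuffled, these splits test for no genotype effect at either age, not for no difference of effects. With 15 libraries 1 of 35 gave as many at E15.5 (306 genes, highest other 3), for age in WT (4655, highest other 1) and for age in KO (4350, highest other 1424, a near mirror of the real split that moved KO E15.5 replicate 3). At E13.5 with 15 libraries 3 of 35 did (1 gene, again Inhba, highest other 2), so chance was not excluded for that count.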

How the results depend on the processing

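Chosen only after the result was seen were the combinations of leaving out KO E13.5 replicate 1 with DESeq2, limma-voom, RLE, only the groups compared, germ cell and erythroid genes left out, or a further library left out. No named gene that was called in either of the settings compared turned its direction at either age. Of the results of named genes other than Inhba, 1118 stayed on the same side of the threshold at E13.5. All of those were uncalled in both settings, since Inhba was the only gene called at that age. At E15.5 1500 stayed, 65 passed newly and 82 were lost. For list results, 583 stayed at E13.5, 33 passed newly, 26 were lost and 7 that were called in either setting turned direction, and at E15.5 604 stayed, 38 passed newly and 7 were lost. Depth limits low genes most in KO E13.5 replicate 3 (6131592 counts), and the median SE at E15.5 was 0.271 with KO E13.5 replicate 1 and 0.183 without it, while the count at E13.5 was 1 in both fits. No paired analysis was possible because the replicate numbers were given in accession order and pair no samples. The title number as a random block in limma-voom (estimated correlation 0.703) gave 123 genes at E15.5, 1862 for age in KO and 1 near Inhba. Deviations from the group means had r = -0.02 for the pair with 855, where other pairs of a WT and a KO library at E15.5 had -0.27 to 0.23. The pair with 1052 had r = -0.09, the highest of the KO E15.5 pairs (others -0.50 to -0.16), in which a shared mean of 4 libraries makes values negative on average. This did not decide whether libraries with the same number deviate together. Except where a reason is given, the cause was not tested.

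With RLE the E15.5 lists of myoid and immediate early genes passed (adjusted p = 0.0471 each), and without erythroid genes they passed at 0.0491 each. With no filter on low counts, Leydig (0.0323), myoid (0.045), neural crest (0.0279) and Notch and Wnt genes (0.0279) passed at E13.5, cholesterol genes (0.0544) were lost, and myoid genes passed at E15.5 (0.0495). With CPM of at least 1 in at least 4 libraries, TGF-beta superfamily (0.0487) and Notch and Wnt genes (0.0487) passed at E13.5 and immediate early genes (0.0366) at E15.5. With limma-voom, Leydig (0.0257), myoid (0.0389) and Notch and Wnt genes (0.0389) passed at E13.5 and myoid genes (0.0345) at E15.5, and 2 genes were called for the difference of effects. DESeq2 called 53 genes at E13.5, 106 at E15.5, 17 for the difference, 2385 for age in WT and 3 genes at both ages.

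Sample quality weights in limma-voom gave KO E13.5 replicate 1 a weight of 0.04 and called 2 genes at E13.5, 546 at E15.5, 15 for the difference, 6441 for age in WT, 5184 for age in KO and 2 near Inhba. At E13.5 the activin responsive (0.0301), Sertoli (0.0171), mitosis (0.0718) and matrix lists (0.302) turned direction, and of these the Sertoli list was called both ways. Stromal (0.171), germ cell (0.157) and hedgehog genes (0.113) were lost, and fatty acid (0.00087), macrophage (1.22e-06), erythroid (0.0356), neural crest (0.0264) and immediate early genes (1.22e-06) passed. At E15.5 macrophage genes passed (0.0222) and Notch and Wnt genes were lost (0.0518).

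With only the libraries of the groups compared, 171 genes were called at E15.5, where KO E13.5 replicate 1 no longer enters, 4560 for age in WT and 336 for age in KO. Sertoli genes at E13.5 were lost (0.0534), and myoid and immediate early genes passed at E15.5 (0.00996 each). A log2 fold change of at least 1 left 909 genes for age in WT and 1576 in KO, as fewer genes can pass. With the 2 KO E15.5 libraries of 1 title number summed, which leaves fewer samples, 13 genes were called at E15.5, 1 for the difference and 1372 for age in KO, and Sertoli genes at E13.5 (0.0638) and Notch and Wnt genes at E15.5 (0.0562) were lost. With an estimated correlation the Sertoli, cholesterol, mitosis, stromal, germ cell, hedgehog and matrix calls at E13.5 were lost (0.966 each), as were mitosis and Notch and Wnt at E15.5 (0.992 each).

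Without KO E13.5 replicate 1, DESeq2 called 168 genes at E13.5, 638 at E15.5, 79 for the difference, 5294 for age in WT, 4945 for age in KO, 20 at both ages and 3 near Inhba. There limma-voom called 340 at E15.5, 7 for the difference, 4909 for age in WT and 2 near Inhba, RLE 305, 18, 4659 and 1, and the fit without germ cell and erythroid genes 316, 17, 4768 and 1.

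Leaving out libraries, the count at E13.5 ranged from 1 to 2 (2 without KO E15.5 replicate 1) and near Inhba from 0 to 3 (without KO E13.5 replicate 1 and WT E15.5 replicate 4). The E15.5 count ranged from 12 (without WT E15.5 replicate 1) to 362 (without KO E13.5 replicate 1 and WT E15.5 replicate 4) and the difference from 1 (without KO E13.5 replicate 4) to 25 (without the same 2 libraries as for 362). Age in WT ranged from 568 (without WT E15.5 replicate 1) to 5227 and age in KO from 1285 (without KO E15.5 replicate 1) to 4748, both highest without KO E13.5 replicate 1 and WT E15.5 replicate 3.

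For the E13.5 lists with adjusted p on both sides of 0.05 on leaving out 1 library, the lowest and highest are given with the KO E13.5 replicate left out, unless WT is named. Lowest without replicate 1 were macrophage (4.2e-08, to 0.969 without 2), immediate early (0.00426, to 0.943 without WT E13.5 replicate 3), fatty acid (0.0268, to 0.969 without 2) and neural crest genes (0.0458, to 0.219 without 2). Highest without replicate 1 were TGF-beta superfamily (0.0214 without 2, to 0.796), stromal (3.19e-05 without 2, to 0.564), myoid (0.0107 without 2, to 0.477 with the direction turned), hedgehog (6.83e-05 without 2, to 0.304), matrix (7.1e-05 without 2, to 0.2 with the direction turned), Notch and Wnt (0.00627 without 2, to 0.702 with the direction turned), Leydig (0.0102 without 4, to 0.321 with the direction turned), mitosis (9.19e-05 without 4, to 0.477 with the direction turned) and germ cell genes (2.82e-09 without 4, to 0.067). Sertoli genes ran from 0.000718 without 4 to 0.0804 without WT E13.5 replicate 3, and turned direction without 1 (0.00785). Cholesterol genes ran from 0.00107 without 3 to 0.298 without 4, and pericyte genes from 0.031 without 2 to 0.822 without WT E13.5 replicate 3.

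For the E15.5 lists with adjusted p on both sides of 0.05 in the same way, WT E15.5 replicate 3, the library with the highest immediate early level of its age, gave the highest adjusted p when left out for Leydig (0.0226 without WT E15.5 replicate 1, to 0.841), immediate early (0.000721 without WT E15.5 replicate 1, to 0.94), myoid (0.0104 without KO E13.5 replicate 1, to 0.256), endothelial (0.00177 without KO E15.5 replicate 4, to 0.634), matrix (0.0426 without WT E15.5 replicate 4, to 0.634) and hypoxia genes (0.0209 without KO E15.5 replicate 3, to 0.341). Fatty acid genes ran from 0.0309 without WT E15.5 replicate 3 to 0.995 without replicate 1, and Notch and Wnt genes from 0.00671 without WT E15.5 replicate 4 to 0.124 without replicate 1. Cholesterol (0.0426 to 0.572) and granulosa genes (0.049 to 0.309) ran from the fit without WT E15.5 replicate 4 to that without KO E15.5 replicate 2.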

Other observations

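Apart from values with 16 libraries, every value in this part was chosen only after the result was seen, from the 15-library fit at E15.5 and from gene lists fixed beforehand. Sertoli markers moved both ways in KO at E15.5, with 6 members higher and 8 lower adjusted over the list alone, of which Cldn11, Aard and Wt1 passed over all genes. The higher members not called over all genes included Sox9, the factor that directs Sertoli fate (log2 fold change 0.42 ± 0.14, edgeR adjusted p over all genes 0.193), Fgf9, a growth factor of the testis (0.52 ± 0.16), and Nr0b1 (0.58). The lower ones were Ptgds, prostaglandin D synthase (-0.56 ± 0.17), Mro (-0.52), Vnn1 (-0.61), Defb19 (-0.51), Gdnf, a growth factor for germ cells (-0.47), Trim47 (-0.61), Tesc (-0.50) and Nedd9 (-0.38). Amh, the anti-Mullerian hormone of Sertoli cells, had -0.10 ± 0.32 (adjusted p = 0.939).

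Among fetal Leydig markers 1 member was higher and 4 were lower adjusted over the list alone, and none passed over all genes. With 16 libraries the mean log2 CPM of this list was 6.42 in WT E15.5 replicate 3, against 5.27 to 5.56 in the other WT and 5.29 to 5.63 in the KO libraries of that age, and camera gave adjusted p = 0.135, and 0.841 without WT E15.5 replicate 3. Aldh1a1, a retinaldehyde dehydrogenase, had -0.83 ± 0.20 (edgeR adjusted p over all genes 0.0543), while the steroid genes Cyp17a1 (-0.24 ± 0.28, adjusted p = 0.809) and Star (-0.19 ± 0.34) and the hormone gene Insl3 (-0.16 ± 0.45) did not pass in either count. The proliferation marker Mki67 (-0.28 ± 0.07, adjusted p = 0.0747) and Top2a, a DNA topoisomerase (-0.35 ± 0.10, adjusted p = 0.0998), were among the 13 mitosis genes lower adjusted over the list alone.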
